A study of Drosophila melanogaster with 16 samples.

How the data were processed

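Gene expression was measured by poly(A) RNA sequencing in 16 libraries of Drosophila NBs and GMCs. The flies carried UAS-dcr2 with ase-GAL4 and UAS-stinger::GFP, so that the driver marks type I NBs with nuclear GFP. Per the labels' protocols, NBs were sorted from larval brains, cultured, and sorted a second time with the GMCs formed, and libraries were made from oligo(dT)-primed cDNA by tagmentation with random octamers in the index as molecular barcodes. Whether the octamers were used in counting is not stated.

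The deposited count of reads per gene is a whole number for 16364 genes in each library, without normalization, followed by 5 summary entries that name no gene. Per the submitters' processing notes, the tools were BWA 0.7.12, TopHat2 2.1.1, bedtools 2.26.0, HTSeq 0.6.1 and DESeq2 1.12.4, with no role given for each. The genome build, the annotation and the strand setting are not given in the sources used here. Of these genes, 16208 were in the reference annotation used here (Ensembl release 115), 16086 of them with the same start and end, and 156 were not. The coordinates printed are those of the reference annotation, release 6 of the genome, which those positions match. Summary entries stayed out of library sizes and tests. Reads in no gene came to a mean of 10.6% to 14.2% by group, ambiguous reads to 1.5% to 2.0%, and reads without a unique alignment to 26.8% to 32.2%. The authors' deposited comparison tables give, per the file headers, a mean signal over all libraries, a log2 fold change of GMCs over NBs with its standard error, a Wald score, a p-value and an adjusted p-value from DESeq2. Their mean signal equals the mean of the 16 libraries over median-ratio size factors within a relative difference of 3.03e-15.

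Libraries were grouped by cell type and age as the labels give them. Differential expression was tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): a quasi-likelihood fit of all 16 libraries in 6 groups with TMM scaling, after filterByExpr (minimum count 10, total 15) kept 10913 genes and removed 5451. The common dispersion was 0.0782. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 9 comparisons were GMCs against NBs at each age, the change of that difference from 1.5 h to 3 h and to 5 h, and each cell type at 3 h and 5 h against 1.5 h. Levels are mean CPM (counts scaled to TMM library sizes) with the SD between libraries. P-values are two-sided. A group of 2 leaves 1 library when the other is left out, which is then taken to vary like the other groups.

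The 25 gene lists, the comparisons, the tests and the alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera on log2 CPM (prior count 2) at its preset correlation of 0.01, with adjustment over all lists and ages. They cover neuroblast identity, Notch targets, Notch pathway components, GMC fate factors, neuron markers, axon guidance, glia markers, hemocyte and fat body markers, type II lineage markers, optic lobe markers, temporal patterning, asymmetric division, DNA replication, mitosis, ribosome biogenesis, ribosomal proteins, V-ATPase subunits, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, heat shock, immediate early and stress genes, JAK-STAT and Toll genes, lysosome and endocytosis, and genes that transgenes carry. The last held 2 members and was not tested as a set. Shared calls between ages were counted against the product of the list sizes over the genes tested.

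The genes to name were set by a rule: for each comparison of GMCs with NBs, the 10 largest fold changes each way among called genes with a mean of at least 20 CPM and no overlap between the groups. For the other comparisons the rule took 5 each way, without the overlap condition for changes of the difference. It added up to 4 members of each list, by smallest adjusted p, and always dpn, ase, wor, mira, pros, N, numb, E(spl)mgamma-HLH, elav, repo and Dcr-2. The rule named 98, 100 and 106 genes for 1.5, 3 and 5 h and 202 distinct genes in all. The text gives 80 of these, chosen after their values were seen, for a known function and for fold changes that held when a library or setting was changed; CR43283 was singled out after its values were seen. The naming therefore leans towards stable genes.

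Tested on simulated data with 10561 genes of which 200 were changed, the test recovered 34%, 15% and 23% of 2-fold changes and 63%, 68% and 62% of 4-fold changes for the designs of 1.5, 3 and 5 h, with 5.83%, 2.35% and 3.41% false calls and 0 calls in the wrong direction. Camera called 2 of 2 changed lists in the right direction and 0 of 67 unchanged ones. The simulated genes varied independently, so this does not test the calls of lists whose members are correlated. Alternatives were median-ratio scaling, DESeq2 1.42.0, no filter on low counts, a replicate block, a fit of only the groups compared, each library left out in turn, an estimated correlation, the fry test and a prior count of 0.5. After the data were examined, scaling without CR43283, removal of a gene-length trend and a fit without all 5 h libraries were added. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.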

Results

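Poly(A) RNA was sequenced from type I neuroblasts (NBs), the stem cells of the Drosophila larval brain, and from ganglion mother cells (GMCs), the smaller daughters that NBs bud off by asymmetric division. NBs were sorted by their fluorescence from brains of wandering larvae and cultured for 1.5, 3 or 5 h, and a second sort then separated the NBs from the GMCs born in culture. The design asks how the daughter cells differ from the stem cells and how GMCs of different ages differ. The 16 libraries formed 6 groups. Each of the 3 NB groups and the GMC group of 1.5 h held 3 libraries, and the GMC groups of 3 h and 5 h held 2 each. Between 6899670 and 21207182 counts per library were assigned to genes. No label says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. By the file names each age was sequenced on its own flow cell. A comparison of GMCs with NBs therefore lies within a run, whereas a change between ages cannot be told apart from a change of run.

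Dcr-2, the RNA interference enzyme that the stock carries as a transgene beside the GFP marker, was far lower at 5 h than at 1.5 h or 3 h. Counts per gene do not separate the transcript of the transgene from that of the fly's own Dcr-2 gene. It stood at 4274 ± 387 CPM in NBs and 10070 ± 2132 CPM in GMCs of 1.5 h (SD, n = 3 each), and at 4349 ± 1521 CPM in NBs (n = 3) and 20610 ± 3402 CPM in GMCs (n = 2) of 3 h. At 5 h it was 296 ± 108 CPM in NBs (n = 3) and 165 ± 19.2 CPM in GMCs (n = 2). It was higher in GMCs than in NBs at 1.5 h (edgeR log2 fold change 1.24, adjusted p = 0.00628) and at 3 h (2.25, adjusted p = 0.000118), but at 5 h the value was -0.85 (adjusted p = 0.0579). The latter passed without NB replicate 1 (edgeR adjusted p = 0.00909), with the gene-length trend removed (edgeR adjusted p = 0.00694) and in DESeq2 (adjusted p = 0.0336). The other gene of the list of genes that transgenes carry, w, the eye colour gene used to mark insertions, had an edgeR log2 fold change of 1.97 at 3 h (adjusted p = 0.000101) and of -1.24 at 5 h (adjusted p = 0.00368), the latter with an adjusted p of 0.0637 without GMC replicate 1. Of these 2 genes, 1, 2 and 1 were called at 1.5, 3 and 5 h over all genes, and 2 at each age when adjusted over the list alone.

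The non-coding RNA CR43283 took 18.7 ± 2.75% of all gene counts in GMCs of 1.5 h (n = 3), 24.6 ± 4.02% in GMCs of 3 h (n = 2) and 9.0 ± 2.91% in GMCs of 5 h (n = 2). In NBs it took 4.58 ± 0.511%, 5.3 ± 1.36% and 0.814 ± 0.304% (SD, n = 3 each). In a principal component analysis of all 16 libraries the first component held 32.3% of the variance and set NB replicates 2 and 3 and both GMC libraries of 5 h (scores of -79, -66.1, -65.1 and -68.2) apart from the rest. NB replicate 1 of 5 h had a score of 38.7, inside the range of the 3 h libraries. The second component held 24% and placed every GMC library below 0 and every NB library above 0.

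**Figure D1:**
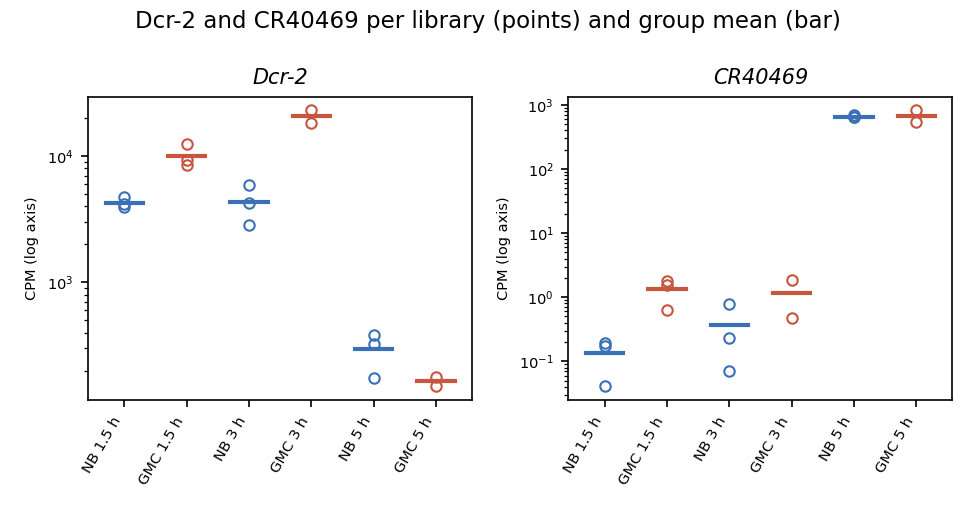
CPM on a log axis of Dcr-2 and the non-coding RNA CR40469 in each library (points) with the group mean (bar), for NBs (blue) and GMCs (red) at 1.5, 3 and 5 h. Dcr-2 is lowest and CR40469 highest in both cell types of 5 h, where CR40469 has means of 657 CPM in NBs and 682 CPM in GMCs.

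**Figure D2:**
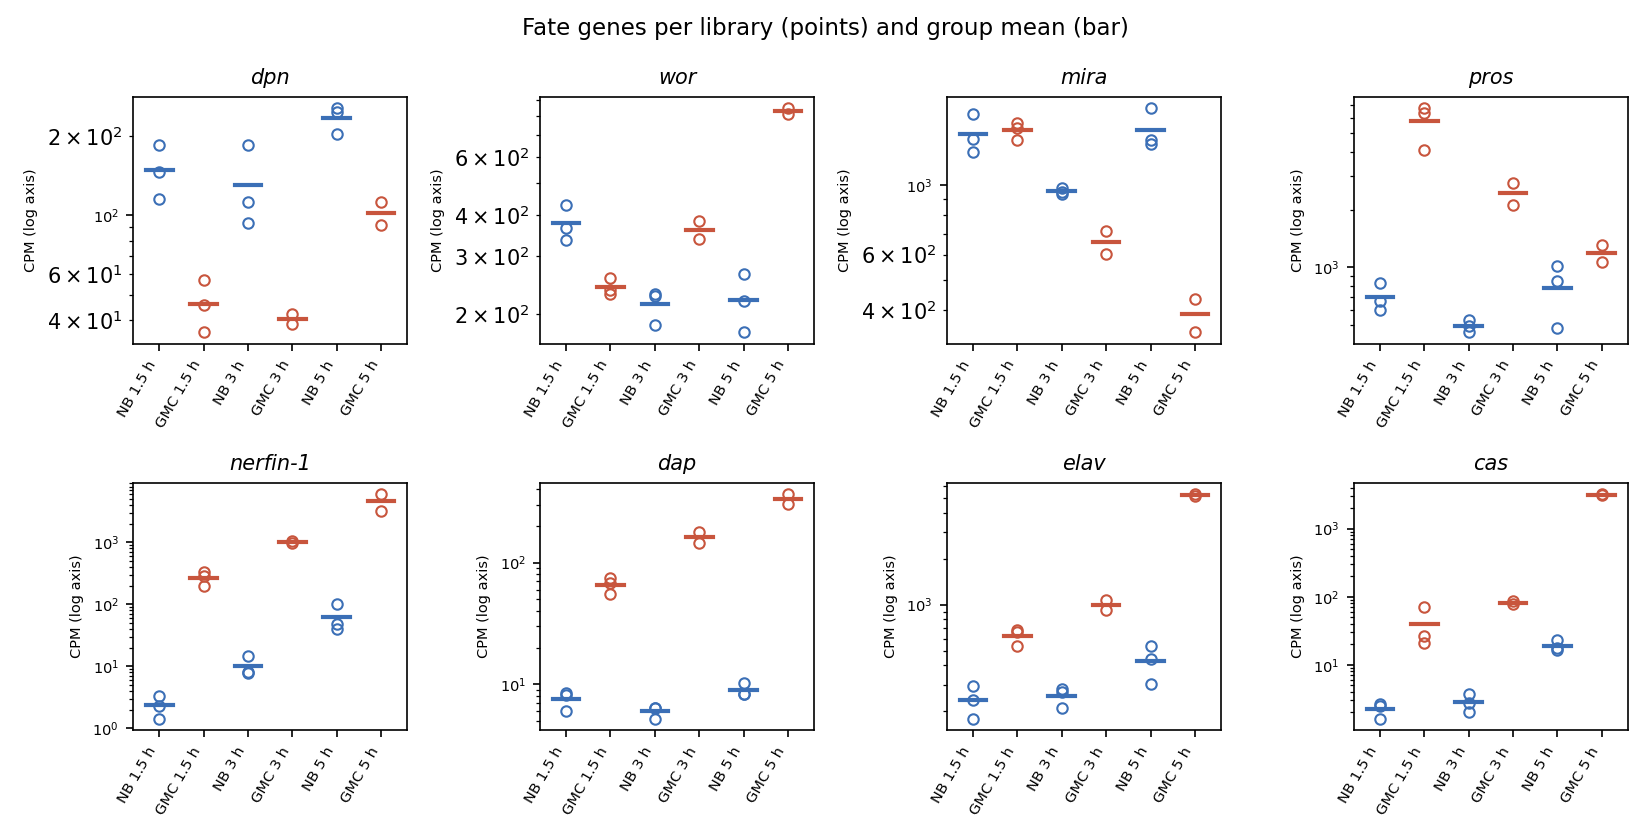
CPM on a log axis of 8 fate genes in each library (points) with the group mean (bar), for NBs (blue) and GMCs (red) at 1.5, 3 and 5 h. The mean of nerfin-1 is 269 CPM in GMCs of 1.5 h and 4669 CPM in GMCs of 5 h, and wor lies below the NBs at 1.5 h (242 CPM) and above them at 5 h (830.3 CPM).

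At 1.5 h, GMCs already carried high levels of genes that drive cells out of the stem cell state. The transcript of nerfin-1 (FBgn0028999, 3L 909112 to 912319 in the release 6 coordinates of the tables), a zinc finger factor that keeps neurons differentiated, stood at 269 ± 66.4 CPM in GMCs and 2.34 ± 0.932 CPM in NBs (SD, n = 3 each), a log2 fold change of 6.83 ± 0.459 (SE). The Cyclin E/Cdk2 inhibitor dap (FBgn0010316, 2R 9712321 to 9716256) stood at 65.9 ± 9.75 CPM against 7.56 ± 1.31 CPM, an 8.73-fold difference. The bHLH factor tap stood at 615 ± 10.7 CPM against 76.4 ± 4.89 CPM. The homeodomain factor pros (FBgn0004595, 3R 11328480 to 11407627), which NBs pass to the GMC and which ends self-renewal, stood at 5743 ± 1442 CPM against 699 ± 116 CPM, 8.22-fold higher. All 4 passed edgeR's quasi-likelihood test (adjusted p = 2.1e-07, 6.45e-08, 1.58e-08 and 3.33e-06). Of the 14 measured GMC fate and neuronal differentiation factors, 10 were higher in GMCs, 2 were lower and 2 were not called, with 12 called when adjusted over the list alone. The list rose as a set against all other genes (median log2 fold change 1.76, camera adjusted p = 2.31e-08), which was lost with adjusted p = 0.131 when the correlation between genes was estimated.

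Stem cell genes were lower in the same GMCs. The bHLH repressor dpn (FBgn0010109, 2R 8228971 to 8232330), a self-renewal factor and Notch target, stood at 46.2 ± 10.4 CPM in GMCs and 149 ± 34.9 CPM in NBs (SD, n = 3 each; edgeR adjusted p = 0.00028). The zinc finger self-renewal factor klu fell by 1.38 on the log2 scale (edgeR adjusted p = 0.000287), the polarity adaptor insc by a log2 fold change of -1.34 (edgeR adjusted p = 0.000939) and the Notch target E(spl)mgamma-HLH by -1.70 (edgeR adjusted p = 0.00159). The Snail family factor wor fell to 242 ± 14.1 CPM from 378 ± 48.1 CPM (edgeR adjusted p = 0.013), but not without NB replicate 1 (adjusted p = 0.0692) or GMC replicate 1 (0.0547). The cargo adaptor mira (edgeR log2 fold change 0.04, adjusted p = 0.906) and the proneural factor ase (0.16, adjusted p = 0.584), whose regulatory region drives the sorting marker, did not pass. Of 15 neuroblast identity genes 1 was higher and 8 were lower, 9 in all when adjusted over the list alone. The set was lower. Their median was -0.64 (camera adjusted p = 0.00112, adjusted p = 0.411 with an estimated correlation). Another annotated gene, CR44275, overlaps 59.28% of the exon length of dpn, and the strand used in counting is not given in the sources used here. The counts of dpn may therefore hold reads of CR44275, or lack reads that were set aside as ambiguous.

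Neuronal genes were high in GMCs of 1.5 h. The pan-neuronal RNA-binding protein elav (FBgn0260400, X 509235 to 523226) stood at 626 ± 78.4 CPM against 238 ± 57.7 CPM in NBs (SD, n = 3 each; edgeR adjusted p = 0.000489). The active zone protein brp stood at 51.9 ± 18.7 CPM against 2.1 ± 0.591 CPM (edgeR adjusted p = 4.98e-05). The gene nrv3, a Na,K-ATPase subunit of neurons, stood at 51.7 ± 9.86 CPM against 0.321 ± 0.114 CPM, with an edgeR log2 fold change of 7.30 (adjusted p = 8.73e-06). Of 21 neuron markers 17 were higher, 0 lower and 4 not called, and 19 were called when adjusted over the list alone. The set rose. Their median was 2.91 (camera adjusted p = 8.75e-13, adjusted p = 0.131 with an estimated correlation). Axon guidance and adhesion genes rose beside them, 17 of 32 and 20 when adjusted over the list alone. Among them were the ligand NetB (edgeR log2 fold change 2.95, adjusted p = 6.69e-05) and the cadherin CadN (2.72, adjusted p = 0.000321). The median of that set was 0.85 (camera adjusted p = 3.57e-08, adjusted p = 0.353 with an estimated correlation). The strand limit applies to elav as well, since 27.94% of its exons overlap another gene.

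Cell cycle and glucose metabolism genes were lower in GMCs of 1.5 h. The phosphatase stg, which triggers entry into mitosis, stood at 208 ± 21.8 CPM against 758 ± 47.6 CPM in NBs (SD, n = 3 each; edgeR adjusted p = 9.34e-05). The mitotic cyclin CycB3 stood at 260.0 ± 31.6 CPM against 914 ± 31.5 CPM (edgeR adjusted p = 2.19e-06). The G1/S cyclin CycE stood at 282 ± 48.3 CPM against 912 ± 95.3 CPM (edgeR adjusted p = 0.000341). Of 47 DNA replication and G1/S genes 19 were lower and 1, dap, was higher, 29 in all when adjusted over the list alone. The set had a median of -0.52 (camera adjusted p = 2.11e-08, adjusted p = 0.26 with an estimated correlation). Of 55 G2/M and mitosis genes 12 were lower and 3 higher, 16 when adjusted over the list alone. Their median was -0.26 (camera adjusted p = 0.00247, adjusted p = 0.51 with an estimated correlation). The glycolytic enzyme Ald (FBgn0000064, 3R 26254069 to 26261591) stood at 102 ± 13.2 CPM against 329 ± 39.1 CPM (edgeR adjusted p = 4.35e-05). Of 12 glycolysis genes 5 were lower and 7 not called, with 8 when adjusted over the list alone. Their median was -0.62 (camera adjusted p = 3.3e-05, adjusted p = 0.262 with an estimated correlation). Ribosome biogenesis factors were lower in 7 of 34 cases, such as Nnp-1 (edgeR log2 fold change -0.68, adjusted p = 0.00198), and in 8 when adjusted over the list alone. Their median was -0.15 (camera adjusted p = 0.0077, adjusted p = 0.672 with an estimated correlation).

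Glia markers and temporal patterning genes were higher in GMCs of 1.5 h as sets. The glial determinants gcm (3.68 ± 1.22 CPM against 0.821 ± 0.347 CPM; edgeR adjusted p = 0.00295) and repo (3.38 ± 1.25 CPM against 0.936 ± 0.182 CPM; edgeR adjusted p = 0.0112) were higher at low levels (n = 3 each). Of these, repo lost its call without NB replicate 2 (adjusted p = 0.0572), NB replicate 3 (0.05) or GMC replicate 2 (0.0667). Of 15 tested glia markers 4 were higher, 6 when adjusted over the list alone. Their median was 0.58 (camera adjusted p = 0.00664, adjusted p = 0.131 with an estimated correlation). Of 16 tested temporal patterning genes 5 were higher and 1 lower, 7 when adjusted over the list alone. Their median was 0.55 (camera adjusted p = 0.00954, adjusted p = 0.235 with an estimated correlation). They included the zinc finger factor cas, with an edgeR log2 fold change of 4.13 (adjusted p = 1.11e-05) that was 3.31 without GMC replicate 3. Of 88 cytosolic ribosomal protein genes 0 were called (0 when adjusted over the list alone) and RpL5 had a log2 fold change of -0.31 (edgeR adjusted p = 0.231). The set test gave a rise (median 0.30, camera adjusted p = 0.0077, adjusted p = 0.858 with an estimated correlation), which was lost without NB replicate 3 (0.323), GMC replicate 1 (0.0706) or GMC replicate 3 (0.0952).

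Over all 10913 genes tested, 937 were higher and 979 lower in GMCs of 1.5 h, a total of 1916 (edgeR, adjusted p under 0.05). Scaling without CR43283 turned that balance, with 1038 higher and 807 lower, and removing the gene-length trend gave 927 and 1213. The CPM values of the GMC and NB libraries did not overlap for 4654 genes, or 42.7%, where chance gives 10% for 3 against 3. Genes are not independent replicates, so a share above chance is no test of cell type. NBs of 3 h against 1.5 h, also 3 against 3, gave 28.2% with 11 genes called. For GMCs against NBs of 1.5 h, leaving out NB replicate 1, NB replicate 2 or GMC replicate 2 left 1157, 1181 and 1219 calls. There 3001 genes were called when only these 2 groups were fitted.

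At 3 h the same fate genes were again higher in GMCs. There nerfin-1 reached 1025 ± 65.8 CPM (SD, n = 2) against 10.2 ± 3.92 CPM in NBs (n = 3), and dap 162 ± 23.4 CPM against 5.98 ± 0.658 CPM. The level of tap was 368 ± 17.1 CPM against 59.6 ± 7.95 CPM, and that of pros 2436 ± 459 CPM against 496 ± 36.6 CPM. Their edgeR log2 fold changes were 6.64, 4.76, 2.63 and 2.30 (adjusted p = 2.23e-07, 1.12e-09, 9.44e-08 and 4e-05), that of pros 1.44 with the gene-length trend removed. Of the 14 GMC fate factors 10 were higher and 0 lower, 11 when adjusted over the list alone. Their median was 1.94 (camera adjusted p = 1.34e-07, adjusted p = 0.131 with an estimated correlation). The pan-neuronal elav stood at 999 ± 106 CPM against 252 ± 37.1 CPM (edgeR adjusted p = 4e-05). Of the neuron markers, 14 of 21 were higher and 0 lower, 17 when adjusted over the list alone. Their median was 1.99 (camera adjusted p = 1.2e-06, adjusted p = 0.28 with an estimated correlation). Axon guidance and adhesion genes were higher in 11 of 32 cases, 13 when adjusted over the list alone (median 0.93, camera adjusted p = 2.98e-05, adjusted p = 0.487 with an estimated correlation), such as the adhesion protein Nrt (edgeR log2 fold change 1.93, adjusted p = 3.1e-05), of whose exons 21.84% overlap another gene.

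The stem cell genes went both ways at 3 h. For the change of the difference between GMCs and NBs from 1.5 h to 3 h, edgeR called 0 genes, while DESeq2 called ase and wor. In GMCs dpn (40.5 ± 2.62 CPM against 130.1 ± 47.9 CPM; edgeR adjusted p = 0.000664), CycE (125 ± 3.05 CPM against 519 ± 66.6 CPM; edgeR adjusted p = 0.000187) and the transcription factor grh (205 ± 15.4 CPM against 497 ± 61.4 CPM; edgeR adjusted p = 0.00177) were lower. Higher in GMCs was ase, at 814 ± 57.8 CPM against 314 ± 55.2 CPM (n = 2 and 3; edgeR adjusted p = 0.000131). The Snail family factor wor was also higher in GMCs, 361 ± 32.1 CPM against 214 ± 25.4 CPM (edgeR adjusted p = 0.00741), a call not kept without GMC replicate 2, which leaves 1 GMC library (log2 fold change 0.65). The adaptor mira had a log2 fold change of -0.53 (edgeR adjusted p = 0.0516), which passed with median-ratio scaling (adjusted p = 0.0266), scaling without CR43283 (0.015), the gene-length trend removed (0.0127), no 5 h libraries in the fit (0.0314) and in DESeq2 (adjusted p = 0.00364). Of 15 neuroblast identity genes 4 were higher and 7 lower, 12 when adjusted over the list alone, and the set was not called. Their median was -0.55 (camera adjusted p = 0.0928, adjusted p = 0.697 with an estimated correlation).

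Replication, glycolysis and proton pump genes were lower in GMCs of 3 h. The licensing factor dup (145 ± 23.3 CPM against 510 ± 46.0 CPM; edgeR adjusted p = 3.18e-06) and the helicase subunit Mcm6 (120.0 ± 9.58 CPM against 467 ± 79.7 CPM; edgeR adjusted p = 5.94e-06) were among 28 of 47 DNA replication genes that were lower (n = 2 and 3). Another 2 were higher, and 35 were called when adjusted over the list alone. Their median was -0.93 (camera adjusted p = 1.73e-11, adjusted p = 0.198 with an estimated correlation). Mitotic genes did not move as a set, with 7 of 55 higher, 11 lower and 18 called when adjusted over the list alone (median -0.14, camera adjusted p = 0.11). Single members were lower, such as stg (edgeR log2 fold change -2.50, adjusted p = 2.45e-05) and CycB3 (-2.42, adjusted p = 8.1e-07). The glycolytic enzymes Ald (46.5 ± 8.42 CPM against 273 ± 36.2 CPM; edgeR adjusted p = 3.18e-06) and Hex-A (47.8 ± 15.1 CPM against 194 ± 54.9 CPM; edgeR adjusted p = 0.000767) were among 8 of 12 glycolysis genes that were lower, 10 when adjusted over the list alone. Their median was -1.13 (camera adjusted p = 9.73e-07, adjusted p = 0.211 with an estimated correlation). The transcription factors apt (74.8 ± 1.6 CPM against 423 ± 32.3 CPM; edgeR adjusted p = 2e-06) and REPTOR, an effector of TORC1 signalling (43.9 ± 9.02 CPM against 234 ± 20.7 CPM; edgeR adjusted p = 2.07e-05), were lower as well.

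Markers used for other lineages were higher in GMCs of 3 h. The factor opa, a mark of intermediate progenitors of type II lineages, stood at 31.4 ± 7.9 CPM against 4.56 ± 0.855 CPM (edgeR adjusted p = 6.9e-06) and ham at 5.36 ± 0.648 CPM against 0.339 ± 0.0512 CPM (n = 2 and 3; edgeR adjusted p = 0.000264). Of 7 tested type II lineage markers 4 were higher and 1 lower, 6 when adjusted over the list alone. Their median was 1.38 (camera adjusted p = 0.00534, adjusted p = 0.131 with an estimated correlation). Of 14 optic lobe markers 8 were higher and 1 lower, 11 when adjusted over the list alone. They included slp2 (71.7 ± 0.743 CPM against 21.3 ± 0.402 CPM; edgeR adjusted p = 4.97e-05) and Optix (32.4 ± 1.63 CPM against 10.7 ± 3.48 CPM; edgeR adjusted p = 0.000201), with a median of 1.05 (camera adjusted p = 0.000536, adjusted p = 0.214 with an estimated correlation). The glial factor repo stood at 1.92 ± 0.579 CPM against 1.77 ± 0.305 CPM (edgeR adjusted p = 0.888). The glia list, with 5 of 15 higher and 7 called when adjusted over the list alone, was not called (median 0.56, camera adjusted p = 0.0534; 0.0157 without GMC replicate 1, just under 0.05 without NB replicate 3 and 0.0464 with a prior count of 0.5). Nor were temporal patterning (5 of 16 higher, 1 lower, 7 when adjusted over the list alone; 0.114), ribosome biogenesis (8 of 34 lower, 8 when adjusted over the list alone; 0.114, and 0.0372 without NB replicate 2). Ribosomal proteins (1 of 88 lower, 0 when adjusted over the list alone; camera adjusted p = 0.156) passed without NB replicate 1 (2.93e-10) or GMC replicate 2 (0.0446).

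In all, 1110 genes were higher and 1145 lower in GMCs of 3 h, a total of 2255 (edgeR). The libraries of the groups did not overlap for 5468 genes, or 50.1%. Chance gives 20% for 2 against 3, and GMCs of 3 h against GMCs of 1.5 h, also 2 against 3, gave 47.9%. The total was 1095 without GMC replicate 1 and 1199 without GMC replicate 2. Scaling without CR43283 gave 39.14% higher calls in place of 49.22% and shifted the median fold change of all genes by -0.106 on the log2 scale.

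At 5 h, single temporal and fate factors were higher in GMCs. The zinc finger factor cas (FBgn0004878, 3R 5712975 to 5716805) stood at 3164 ± 97.1 CPM in GMCs (SD, n = 2) and 19.1 ± 3.43 CPM in NBs (n = 3), an edgeR log2 fold change of 7.37 ± 0.448 (SE, adjusted p = 3.27e-08). The temporal factor chinmo stood at 806 ± 314 CPM against 79.3 ± 28.3 CPM (edgeR adjusted p = 1.3e-06). Temporal patterning genes as a set were not called, with 4 of 16 higher, 1 lower and 6 when adjusted over the list alone (median 0.17, camera adjusted p = 0.104; 0.0211 without GMC replicate 1). The fate genes nerfin-1 (4669 ± 1975 CPM against 62.7 ± 32.3 CPM; edgeR adjusted p = 1.18e-07), dap (335 ± 45.0 CPM against 8.94 ± 1.13 CPM; edgeR adjusted p = 2.81e-10) were higher. So were tap (1241 ± 40.7 CPM against 147 ± 22.8 CPM; edgeR adjusted p = 1.24e-08) and the BTB factor lola (7861 ± 926 CPM against 1765 ± 241 CPM; edgeR adjusted p = 3.88e-07). The value of pros was 1186 ± 175 CPM against 784 ± 270.3 CPM (edgeR log2 fold change 0.60, adjusted p = 0.115), with an adjusted p of 0.0465 without NB replicate 3. Of the 14 GMC fate factors 8 were higher and 1 lower, 11 when adjusted over the list alone. Their median was 1.57 (camera adjusted p = 1.64e-06, adjusted p = 0.131 with an estimated correlation).

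The neuron markers were not called as a set at 5 h. In GMCs elav stood at 5216 ± 114.7 CPM against 426 ± 117 CPM (n = 2 and 3; edgeR adjusted p = 8.39e-08). Its relative fne stood at 354 ± 23.8 CPM against 93.3 ± 57.9 CPM (edgeR adjusted p = 0.0012). Only 4 of 21 were higher, 2 were lower and 15 were not called, with 8 when adjusted over the list alone (median 0.00, camera adjusted p = 0.333). In NBs themselves 10 of the 21 were higher at 5 h than at 1.5 h and 0 lower, 12 when adjusted over the list alone (median 1.29). For the 11 members under 5 CPM in NBs of 1.5 h, NB replicate 3 of 5 h had a mean of 17.5 CPM, against 3.97 and 3.3 CPM in NB replicates 1 and 2. The set test gave an adjusted p of 0.0257 without NB replicate 3 and of 0.0456 without GMC replicate 1. Axon guidance and adhesion genes were higher in 14 of 32 cases and lower in 1, 16 when adjusted over the list alone (median 0.93, camera adjusted p = 4.06e-05, adjusted p = 0.487 with an estimated correlation). They included Nrt (1773 ± 254 CPM against 333 ± 90.4 CPM; edgeR adjusted p = 1.74e-06) and Dscam1, a cell recognition receptor of neurons (928 ± 145 CPM against 128 ± 30.1 CPM; edgeR adjusted p = 1.79e-06).

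Stem cell genes went both ways in GMCs of 5 h. The Snail family factor wor (FBgn0001983, 2L 15423297 to 15425580) was 3.77-fold higher, at 830.3 ± 27.6 CPM against 220.1 ± 44.6 CPM (edgeR adjusted p = 1.87e-06), and ase was 3.28-fold higher (edgeR adjusted p = 8.22e-06). The repressor zfh1 stood at 41.4 ± 6.14 CPM against 4.68 ± 1.68 CPM (n = 2 and 3; edgeR adjusted p = 7.27e-06). The adaptor mira (FBgn0021776, 3R 19931799 to 19935120), at 387 ± 67.1 CPM against 1500 ± 228 CPM (edgeR adjusted p = 3.06e-06), and CycE, at 112 ± 48.0 CPM against 1051 ± 340 CPM (edgeR adjusted p = 2.51e-06), were lower. So was dpn, at 102 ± 14.3 CPM against 234 ± 28.1 CPM (edgeR adjusted p = 0.00374), with an adjusted p of 0.0589 without GMC replicate 1. Of 15 neuroblast identity genes 4 were higher and 5 lower, 9 when adjusted over the list alone (median -0.16, camera adjusted p = 0.911).

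Replication and glycolysis genes were lower in GMCs of 5 h, with medians further below 0 than at 1.5 h or 3 h. For replication, dup (60.2 ± 0.545 CPM against 405 ± 14.2 CPM; edgeR adjusted p = 3.64e-08) and Mcm6 (70.3 ± 10.7 CPM against 365 ± 51.3 CPM; edgeR adjusted p = 5.89e-07) were among 29 of 47 genes that were lower (n = 2 and 3). Another 4 were higher, and 38 were called when adjusted over the list alone. Their median was -1.08 (camera adjusted p = 1.8e-10, adjusted p = 0.211 with an estimated correlation). Of 55 G2/M and mitosis genes 18 were higher and 9 lower, 27 when adjusted over the list alone (median 0.23, camera adjusted p = 0.158, 0.0127 without NB replicate 2). The condensin subunit Cap-G (768 ± 84.7 CPM against 157 ± 75.8 CPM; edgeR adjusted p = 3.69e-05) and rap, the activator of the anaphase-promoting complex that holds cells in G1 (442 ± 10.8 CPM against 137 ± 13.1 CPM; edgeR adjusted p = 8.31e-07), were higher. CycB3 was lower (222 ± 3.09 CPM against 763 ± 72.0 CPM; edgeR adjusted p = 2.77e-06). In glycolysis 11 of 12 genes were lower, 12 when adjusted over the list alone (median -1.78, camera adjusted p = 1.61e-09, adjusted p = 0.131 with an estimated correlation). Among them Ald stood at 19.4 ± 5.76 CPM against 330 ± 48.6 CPM (edgeR adjusted p = 3.39e-08), Gapdh2 at 104 ± 15.1 CPM against 437 ± 46.9 CPM (edgeR adjusted p = 5.89e-07) and pyruvate kinase PyK at 57.8 ± 3.44 CPM against 261 ± 33.5 CPM (edgeR adjusted p = 9.81e-07).

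Other markers were higher in GMCs of 5 h as well. Of 7 type II lineage markers 5 were higher and 0 lower, 5 when adjusted over the list alone. Of these, opa stood at 30.5 ± 1.53 CPM against 5.18 ± 1.06 CPM (n = 2 and 3; edgeR adjusted p = 5.72e-06), and the list had a median of 1.55 (camera adjusted p = 0.000358, adjusted p = 0.131 with an estimated correlation). Of 14 optic lobe markers 10 were higher and 0 lower, 10 when adjusted over the list alone (median 1.29, camera adjusted p = 4.48e-05, adjusted p = 0.157 with an estimated correlation). Among them were dac (198 ± 40.2 CPM against 51.5 ± 12.1 CPM; edgeR adjusted p = 1.03e-05) and Optix (57.1 ± 1.8 CPM against 14.7 ± 2.52 CPM; edgeR adjusted p = 1.49e-05). The glial genes gcm (21.5 ± 6.67 CPM against 1.65 ± 0.574 CPM; edgeR adjusted p = 2.72e-05) and the glutamate transporter Eaat1 (676 ± 7.68 CPM against 266 ± 47.9 CPM; edgeR adjusted p = 7.07e-05) were higher. The glial factor repo was not called at 5 h (0.988 ± 0.0329 CPM against 2.07 ± 1.18 CPM; edgeR adjusted p = 0.17). The glia list, with 5 of 15 higher, 1 lower and 6 when adjusted over the list alone, was not called (median 0.73, camera adjusted p = 0.11). Ribosome biogenesis (1 of 34 higher, 6 lower, 6 when adjusted over the list alone; camera adjusted p = 0.114) and ribosomal proteins (1 of 88 lower, 0 when adjusted over the list alone; 0.0649) were not called either. The first passed without NB replicate 1 (0.0111) or GMC replicate 2 (0.0274), the second without GMC replicate 2 (0.000257).

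In all, 1618 genes were higher and 1526 lower in GMCs of 5 h, a total of 3144 (edgeR). Scaling without CR43283 gave 58.2% higher calls in place of 51.46%. The total was 1742 without GMC replicate 2. The libraries of the groups did not overlap for 5225 genes, or 47.9%. Chance gives 20% for 2 against 3, and GMCs of 5 h against GMCs of 1.5 h, also 2 against 3, gave 61.3%.

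Notch genes were followed because the pathway sets NB identity. Its receptor N stood at 553 ± 128 CPM in GMCs and 336 ± 83.0 CPM in NBs of 1.5 h (n = 3 each; edgeR adjusted p = 0.0377), a call lost without NB replicate 1 (adjusted p = 0.165), NB replicate 3 (0.102), GMC replicate 1 (0.184) or GMC replicate 2 (0.0808), with no filter on low counts (0.0551) or with the gene-length trend removed (0.125). It was not called at 3 h (edgeR adjusted p = 0.0804) or 5 h (edgeR adjusted p = 0.112; 0.0475 without NB replicate 2 and 0.0436 with scaling without CR43283). The Notch inhibitor numb stood at 454 ± 87.8 CPM in GMCs and 703 ± 139 CPM in NBs of 1.5 h (edgeR adjusted p = 0.045), a call lost without any of the libraries except GMC replicate 1 (adjusted p 0.0502 to 0.221) or with scaling without CR43283 (0.0527). It was not called at 3 h (edgeR adjusted p = 0.754) or 5 h (edgeR adjusted p = 0.405). The Notch target E(spl)mgamma-HLH (FBgn0002735, 3R 25999851 to 26000761) was lower in GMCs at 1.5 h and at 3 h (edgeR log2 fold change -1.88, adjusted p = 0.00193) and not at 5 h (0.38, adjusted p = 0.428). At 5 h other targets of the complex were higher in GMCs: E(spl)m8-HLH (224 ± 19.8 CPM against 16.5 ± 1.25 CPM; edgeR adjusted p = 8.22e-06), E(spl)m7-HLH (130.3 ± 56.0 CPM against 5.63 ± 1.46 CPM; edgeR adjusted p = 1.74e-06) and E(spl)mbeta-HLH (129.8 ± 32.0 CPM against 12.5 ± 2.81 CPM; edgeR adjusted p = 6.65e-07). From 1.5 h to 5 h their difference between GMCs and NBs changed by 1.74, 2.66 and 2.61 on the log2 scale. Each change was smaller than the difference at 5 h, so the estimates for 1.5 h lay above 0 as well.

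Of 12 tested Notch targets 4 were higher and 4 lower at 1.5 h (8 when adjusted over the list alone; camera adjusted p = 0.683), 2 and 4 at 3 h (7; 0.618), and 5 and 2 at 5 h (7; median 1.05, 0.0496, adjusted p = 0.28 with an estimated correlation). At 1.5 h the median of these targets (-0.40) and their mean (0.27) differ in sign. The call at 5 h was lost without NB replicate 1 (adjusted p = 0.0922), NB replicate 3 (0.0629) or GMC replicate 1 (0.0921) and with a prior count of 0.5 (0.0603). Of 27 Notch pathway components 4 were higher and 3 lower at 1.5 h (10 when adjusted over the list alone; camera adjusted p = 0.333). There were 7 and 0 at 3 h (7; median 0.29, camera adjusted p = 0.0333, adjusted p = 0.672 with an estimated correlation) and 10 and 0 at 5 h (11; median 0.45, camera adjusted p = 0.00104, adjusted p = 0.466 with an estimated correlation). They included the DNA-binding factor Su(H), at 194 ± 36.7 CPM against 59.7 ± 19.1 CPM at 5 h (edgeR adjusted p = 7.05e-05), and the ligand Dl (378 ± 161 CPM against 130.9 ± 43.3 CPM; edgeR adjusted p = 0.000625). The co-repressor H was higher already at 1.5 h (edgeR log2 fold change 1.90, adjusted p = 4.23e-05).

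Subunits of the V-ATPase, the proton pump of endosomes and lysosomes, were lower in GMCs. Vha100-2 (FBgn0028670, 3R 18390323 to 18399169) stood at 20.7 ± 4.78 CPM against 65.3 ± 5.63 CPM at 1.5 h (n = 3 each; edgeR adjusted p = 0.000123), 6.71 ± 2.03 CPM against 52.9 ± 9.3 CPM at 3 h (n = 2 and 3; edgeR adjusted p = 5.13e-06) and 4.77 ± 0.592 CPM against 69.2 ± 12.98 CPM at 5 h (n = 2 and 3; edgeR adjusted p = 3.12e-07). Vha68-2 had edgeR log2 fold changes of -1.21, -1.65 and -1.60 (adjusted p = 3.64e-05, 4.25e-06 and 2.19e-06). Of 24 tested subunits 7 were lower and 2 higher at 1.5 h (9 when adjusted over the list alone), 10 lower at 3 h (11) and 17 lower at 5 h (18). As a set they were not called at 1.5 h (median -0.25, camera adjusted p = 0.0574; 0.0489 without NB replicate 2 and 0.0176 without NB replicate 3). They were lower at 3 h (median -0.73, camera adjusted p = 8.14e-06, adjusted p = 0.131 with an estimated correlation) and 5 h. Their median was -1.17 (camera adjusted p = 2.31e-08, adjusted p = 0.131 with an estimated correlation). The study itself worked on this complex with these samples, so these counts are not independent evidence of its direction.

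**Figure D3:**
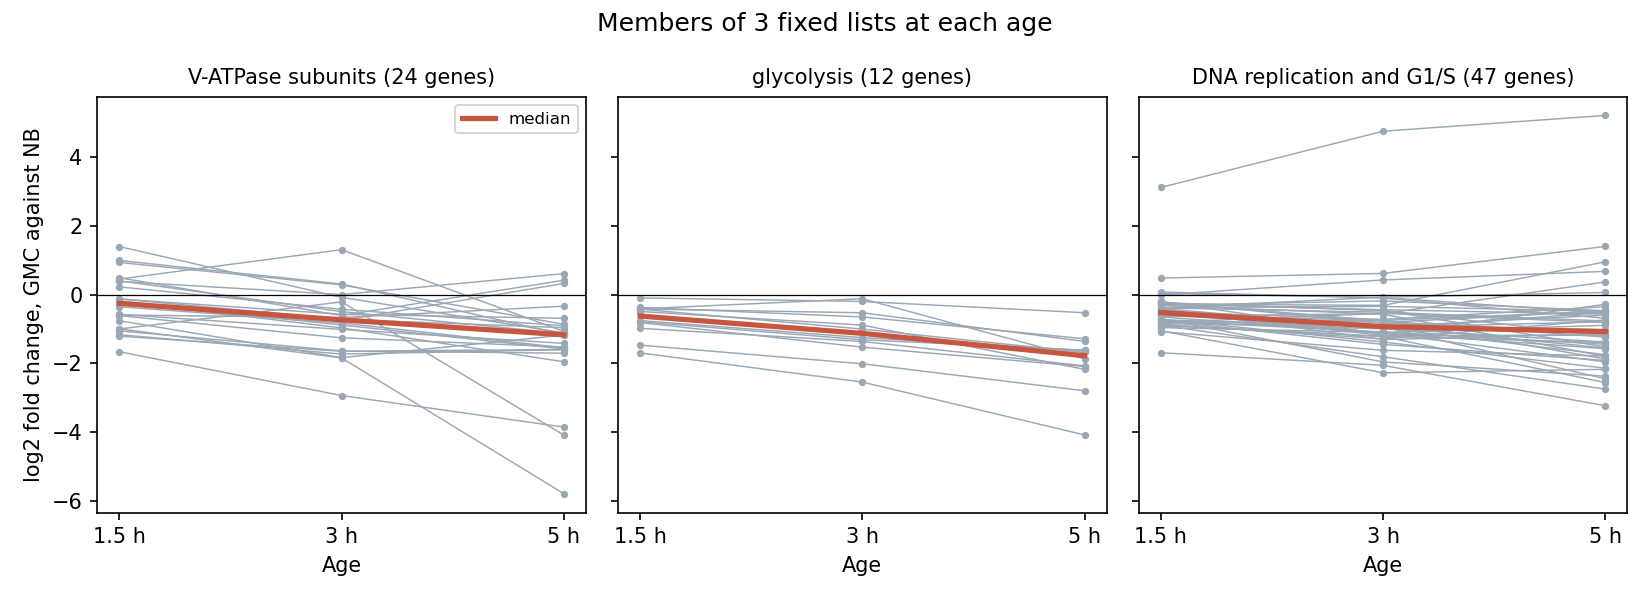
Log2 fold change of GMCs against NBs at 1.5, 3 and 5 h (horizontal axis, age) for each tested V-ATPase, glycolysis and DNA replication gene (grey) and their median (red). The medians at 5 h are -1.17, -1.78 and -1.08, and dap is the replication gene that lies above 5 there.

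**Figure D4:**
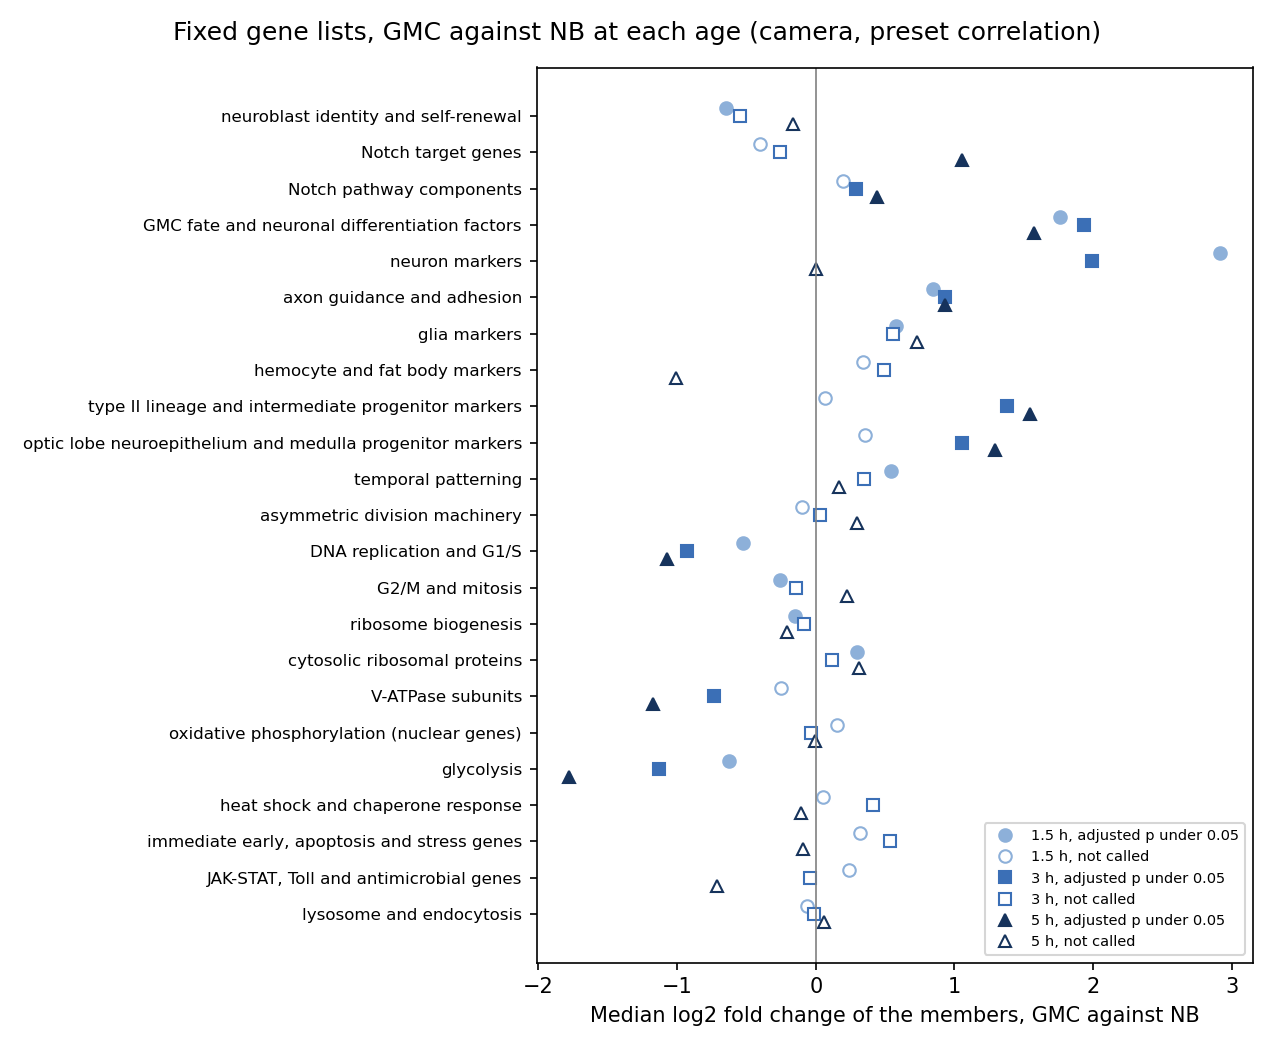
Median log2 fold change (horizontal axis) of the members of 23 gene lists in GMCs against NBs at each age, filled where the camera test with its preset correlation has an adjusted p under 0.05. With an estimated correlation 0 of the lists are called at any age.

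Across the lists, camera with its preset correlation called 11 of 23 lists at 1.5 h (6 higher, 5 lower), 9 at 3 h (6 higher, 3 lower) and 9 at 5 h (6 higher, 3 lower). With an estimated correlation it called 0 at each age. Several lists were not called at any age. Asymmetric division genes had 3 of 30 higher and 7 lower at 1.5 h (10 when adjusted over the list alone; camera adjusted p = 0.253), 6 and 5 at 3 h (12; 0.915) and 10 and 5 at 5 h (17; 0.21). The polarity protein par-6 was lower at 1.5 h (edgeR log2 fold change -1.25, adjusted p = 0.000123) and the myosin jar was higher at 5 h (2.25, adjusted p = 6.17e-07). Hemocyte and fat body markers had 1, 2 and 3 of 15 lower and 0 higher (1, 2 and 3 when adjusted over the list alone; camera adjusted p = 0.669, 0.915 and 0.312). The scavenger receptor crq was lower at each age (edgeR adjusted p = 0.00157, 4e-05 and 0.00232). At 1.5 h, type II markers had 2 of 7 higher and 1 lower (3 when adjusted over the list alone; camera adjusted p = 0.275), opa among them (edgeR adjusted p = 0.00735). At that age optic lobe markers had 3 of 14 higher and 2 lower (7; 0.141), with Optix higher (edgeR adjusted p = 0.00507).

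Mitochondrial, stress, immune and vesicle lists were not called as sets by camera at any age, though single members were. The fry test called the stress list at 3 h (adjusted p = 0.0214) and the JAK-STAT, Toll and antimicrobial list at 5 h (adjusted p = 0.00635). Nuclear oxidative phosphorylation genes had 2, 5 and 3 of 76 called (2, 0 and 3 when adjusted over the list alone; camera adjusted p = 0.269, 0.741 and 0.636), ND-MLRQ being higher at 1.5 h (edgeR adjusted p = 0.00251). The set passed at 1.5 h without NB replicate 1 (0.00635) or GMC replicate 2 (0.0315), at 3 h without NB replicate 1 (0.00108) and at 5 h without GMC replicate 1 (0.0454). Heat shock genes had 3, 3 and 8 of 19 called (3, 3 and 10 when adjusted over the list alone; camera adjusted p = 0.529, 0.258 and 0.303, with 0.0407 at 3 h without NB replicate 1). The small heat shock proteins Hsp26 (96.2 ± 0.812 CPM against 484 ± 81.4 CPM; edgeR adjusted p = 1.35e-05) and Hsp23 (201 ± 16.1 CPM against 807 ± 211 CPM; edgeR adjusted p = 3.54e-05) were lower in GMCs of 5 h. Another, Hsp67Bc, was higher at 1.5 h (edgeR adjusted p = 0.000114). Of 20 immediate early, apoptosis and stress genes 4, 7 and 11 were called (5, 10 and 11 when adjusted over the list alone; camera adjusted p = 0.233, 0.0988 and 0.636, with 0.0459 and 0.0433 at 3 h without NB replicate 1 or GMC replicate 1). The p53 regulator Corp was higher at 1.5 h (edgeR adjusted p = 0.00261). Jra, the fly Jun (edgeR adjusted p = 0.000293), and the stress factor Xrp1 (1424 ± 86.1 CPM against 606 ± 104 CPM; edgeR adjusted p = 0.000843) were higher at 3 h. Of 18 JAK-STAT, Toll and antimicrobial genes 4, 6 and 4 were called (4, 6 and 3 when adjusted over the list alone; camera adjusted p = 0.964, 0.915 and 0.228). Stat92E was lower at each age (edgeR log2 fold change -1.18, -1.55 and -2.18; adjusted p = 0.000123, 3.68e-05 and 8.59e-07) and its feedback inhibitor Socs36E higher at 5 h (1.53, adjusted p = 6.53e-06). Of 32 lysosome and endocytosis genes 2, 3 and 5 were called (1, 3 and 5 when adjusted over the list alone; camera adjusted p = 0.463, 0.636 and 0.964). The adaptor subunit AP-2mu was lower at 1.5 h (edgeR adjusted p = 0.00529). The sign of the median differs from that of the set test for JAK-STAT genes at 1.5 h and 3 h, stress and lysosome genes at 5 h, hemocyte and fat body markers at 1.5 h and oxidative phosphorylation genes at 3 h. The list of mitochondrially encoded genes had 0 members among the genes of the tables used here.

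The change of the difference between GMCs and NBs was tested from age to age, where a shift of equal size in both cells of a run cancels. A shift of run or stock that differs in size between the cells does not cancel. Dcr-2 had log2 fold changes from 1.5 h to 5 h of -3.85 in NBs and -5.93 in GMCs. The changes below therefore cannot be told apart from such a shift. From 1.5 h to 5 h the difference grew in the positive direction for wor (log2 change 2.56), cas (3.24), elav (2.22), ase (1.55), the translation regulator Unr (2.78), the gene sprt (2.87) and E(spl)mgamma-HLH (2.08). It moved the other way for mira, with a log2 change of -1.995, pros (-2.44), Dcr-2 (-2.08) and the RNA-binding protein bru3 (-6.21). Their edgeR adjusted p-values lay between 4.68e-05 for wor and 0.0072 for E(spl)mgamma-HLH, and cas had a log2 change of 4.005 without GMC replicate 3 of 1.5 h. No such change was called for dpn (0.49, edgeR adjusted p = 0.391), N (-0.17, adjusted p = 0.773) or numb (0.90, adjusted p = 0.0624), but numb passed in DESeq2 (0.0275), without GMC replicate 1 of 5 h (0.0345), with scaling without CR43283 (0.0395) and with the gene-length trend removed (0.0145). For repo the value of -2.90 (edgeR adjusted p = 0.0157) lost its call without GMC replicate 1 (0.0664) or 2 (0.0729) of 5 h. In all, 719 genes moved up and 719 down, a total of 1438 (edgeR). That total was 899 without NB replicate 2 of 1.5 h, 805 without GMC replicate 1 of 5 h and 719 without GMC replicate 2 of 5 h. From 1.5 h to 3 h edgeR called 0 genes, with 683 at an unadjusted p under 0.05, and DESeq2 called 32. There wor had a log2 change of 1.40 (edgeR adjusted p = 0.17), ase 1.21 (0.283), mira -0.57 (0.792) and pros -0.74 (0.83). DESeq2 called wor (1.34, adjusted p = 6.2e-05) and ase (1.16, adjusted p = 0.00309).

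Between ages within a cell type, age and sequencing run coincide. In GMCs of 5 h against 1.5 h, cas stood at 3164 ± 97.1 CPM against 39.4 ± 27.9 CPM (n = 2 and 3), with a log2 fold change of 6.33 that was 7.07 without GMC replicate 3 of 1.5 h. There elav stood at 5216 ± 114.7 CPM against 626 ± 78.4 CPM, wor at 830.3 ± 27.6 CPM against 242 ± 14.1 CPM and ase at 1427 ± 234 CPM against 370.2 ± 29.7 CPM. Over the same span pros fell from 5743 ± 1442 CPM to 1186 ± 175 CPM, mira from 1494 ± 93.1 CPM to 387 ± 67.1 CPM and Dcr-2 from 10070 ± 2132 CPM to 165 ± 19.2 CPM. All passed edgeR's test, with adjusted p between 1.27e-07 for cas and 5.12e-05 for pros. The non-coding RNA CR40469, near 0 at 1.5 h, rose in both cell types, to 682 ± 199 CPM from 1.33 ± 0.623 CPM in GMCs (edgeR adjusted p = 4.8e-09) and to 657 ± 30.4 CPM from 0.135 ± 0.0814 CPM in NBs (n = 3 each; edgeR adjusted p = 5.23e-10). In all, 3312 genes were called between GMCs of 5 h and 1.5 h (1860 higher and 1452 lower), with 2150 without GMC replicate 1 of 5 h and 1627 without replicate 2. Fitting only these 2 groups turned the balance, with 2124 higher and 2175 lower.

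In NBs of 5 h against 1.5 h, nerfin-1 rose to 62.7 ± 32.3 CPM from 2.34 ± 0.932 CPM (n = 3 each; edgeR adjusted p = 7.17e-06) and the amino acid enzyme AsnS to 140.2 ± 93.5 CPM from 5.58 ± 1.53 CPM (edgeR adjusted p = 0.000446). Unr fell to 112 ± 45.8 CPM from 1523 ± 153 CPM and the heat shock non-coding RNA Hsromega to 296 ± 30.0 CPM from 2350.0 ± 186 CPM (edgeR adjusted p = 1.73e-06 for each). In the same NBs wor fell by 0.78 on the log2 scale (edgeR adjusted p = 0.00759), while mira had a log2 fold change of 0.05 (adjusted p = 0.883). In all, 794 genes were higher and 437 lower, a total of 1231 (edgeR). That total was 461, 594 and 634 without NB replicates 1, 2 and 3 of 1.5 h, 2285 without NB replicate 1 of 5 h and 481 without replicate 3. The share of higher calls was 50.92% in place of 64.5% when only these 2 groups were fitted.

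From 1.5 h to 3 h fewer genes passed than from 1.5 h to 5 h. In NBs 8 were higher and 3 lower (edgeR), with ImpL3, the lactate dehydrogenase, at 159 ± 97.1 CPM against 15.3 ± 5.18 CPM (n = 3 each; edgeR adjusted p = 0.0284). The lipase bmm stood at 32.0 ± 3.38 CPM against 69.7 ± 5.16 CPM (edgeR adjusted p = 0.0328). That call was lost without any 1 of the 6 libraries (adjusted p 0.0552 to 0.291). Of these 11 calls at most 3 genes were called when any 1 of the 6 libraries was left out, and ImpL3 passed only without NB replicate 2 of 3 h among those 6 fits. In GMCs 144 genes were higher and 179 lower, 323 in all. Among them mira stood at 660.1 ± 77.8 CPM against 1494 ± 93.1 CPM (n = 2 and 3; edgeR adjusted p = 0.00723) and bmm at 12.2 ± 3.62 CPM against 39.5 ± 4.29 CPM (edgeR adjusted p = 0.00301). Leaving out replicate 1, 2 or 3 of 1.5 h left 102, 78 and 52 calls, and leaving out GMC replicate 1 or 2 of 3 h left 4 and 39. Without that replicate 1 the adjusted p was 0.185 for mira and 0.0849 for bmm. The share of higher calls in NBs, 72.73%, was 84.62% with scaling without CR43283, 94.74% with only these 2 groups fitted and 44.19% with the gene-length trend removed. In GMCs the share was 44.58%, with 32.33%, 58.28% and 36.26% in those settings. Hemocyte and fat body markers had a median log2 fold change of 1.57 in GMCs, with 1 of 15 higher and 1 lower, or 5 and 1 when adjusted over the list alone. In NBs the median was 1.34, with 0 called, or 3 higher when adjusted over the list alone.

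The calls of the 3 ages, which share no library, overlapped. They come from 1 fit with a shared spread per gene, so a gene of low spread is easier to call at every age. The sharing of independent lists may therefore be too low a baseline. Of 937 genes higher in GMCs of 1.5 h, 541 were also higher at 3 h, where independent lists would share 95.3, and of 979 lower genes 734 were also lower, against 103; 0 and 1 were called in opposite directions. Between 1.5 h and 5 h, 306 higher and 517 lower genes were shared, against 139 and 137, and 48 and 43 genes were called in opposite directions. Between 3 h and 5 h, 665 higher and 660 lower genes were shared, against 165 and 160.1, and 27 and 11 were called in opposite directions. At all 3 ages 268 genes were higher and 451 lower. Across the 10913 genes, which are not independent replicates, the fold changes of 1.5 h and 3 h had a Pearson r of 0.697 and a Spearman rho of 0.709, those of 1.5 h and 5 h 0.143 and 0.249, and those of 3 h and 5 h 0.318 and 0.386.

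The authors' deposited tables of GMCs against NBs held 2438 genes at 1.5 h, 2845 at 3 h and 3603 at 5 h with an adjusted p under 0.05. Of the genes that edgeR called here, 1911, 2239 and 3100 were also called in the authors' deposited tables in the same direction, or 99.7%, 99.3% and 98.6%, and 0 in the opposite direction. Those tables come from the same libraries, so the sharing is not independent evidence. From their side edgeR called 1911 of 2438, 2239 of 2845 and 3100 of 3603 genes. In the authors' deposited table of 5 h, cas has a log2 fold change of 6.77 (adjusted p = 1.83e-72), wor of 1.90 (adjusted p = 3.34e-26) and pros of 0.61 (adjusted p = 0.0682).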

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

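Every test of an explanation below, and the tests of the change of a list's difference, were chosen only after the results were seen. The values for genes and lists were singled out because the difference between GMCs and NBs changed with age in a test of that change, and NB replicate 1 of 5 h because it stood apart from its group.

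Neuron markers that NBs of 1.5 h barely express were high in GMCs of 1.5 h. They were lower in GMCs of 5 h and higher in NBs of 5 h, so both cell types enter the change of their difference. Choosing members by a low level in NBs of 1.5 h favours a rise in NBs. In the whole list of 21, without that choice, 10 were higher in NBs of 5 h than of 1.5 h and 0 lower (median log2 fold change 1.29). For the 11 of 21 neuron list members under 5 CPM in NBs of 1.5 h, among them brp at 51.9 CPM in those GMCs, the mean log2 CPM was 3.08, 4.03 and 3.96 in the GMC libraries of 1.5 h and 1.27 and 2.32 in those of 5 h, and it was -0.45, -0.56 and -0.03 in NBs of 1.5 h and 1.19, 1.03 and 3.43 in NBs of 5 h. Maturation of the GMC progeny with age stays open, since the change of that mean from 1.5 h to 5 h, -1.89, cannot be told apart from a change of run. Neurons carried through the second sort stay open as well: 90.9% of the members had their lowest value of the 3 libraries in GMC replicate 1, against 33.4% of all tested genes, but so did 9 of 14 GMC fate factors, and a cause shared by both sets would do the same. Differences between the sequencing runs cannot be told apart from age and stay open, as does another biological difference between GMC ages.

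Dcr-2, which the stock carries as a transgene, was low in both cell types at 5 h, and its difference between GMCs and NBs changed by -2.08 from 1.5 h to 5 h. Lower activity of the ase driver stays open. The transcript of ase itself had log2 fold changes of at least 0.397 from 1.5 h to 5 h in both cell types. It does not measure the output of the driver transgene, and a change over that span cannot be told apart from a change of run. Lower depth is argued against. All 5 libraries of 5 h were deeper than a library of another age with over 10 times their Dcr-2 level. Another stock or transgene copy at 5 h may account for it and stays open. Of 28 genes changed over 8-fold in both cell types, CR40469 among them, 20 changed the same way. That lies between the bounds set for and against it. All others rose in NBs and fell in GMCs, the neuronal genes Gad1 and nrv3 among them. The fate genes nerfin-1 (log2 fold change 4.73 in NBs and 4.12 in GMCs) and cas (3.09 and 6.33) were among the 20, as was CG32581 (11.21 and 11.27). Beyond the driver, no biological explanation other than age was available, and age cannot be told apart from run.

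NB replicate 1 of 5 h stood apart from replicates 2 and 3 on the first principal component (38.7 against -79 and -66.1). A swap with a 3 h library is argued against by its CR40469 level of 640.1 CPM, which is near 0 in the 3 h libraries. Greater depth is argued against, since it is the shallowest of the 3 at 7.35 M gene counts and still has 13297 genes with a count. Genomic DNA may contribute and stays open: over 7776 genes under 1 CPM in the other libraries, its excess had a Spearman rho of 0.196 with exon length, too close to the bound of 0.2 to decide. No biological explanation was tested.

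Of the genes named in the report, these changed their difference between GMCs and NBs from 1.5 h to 5 h (log2 change, edgeR adjusted p under 0.05), among 1438 genes in all. Among fate genes the values were 2.099 for dap, -2.44 for pros, 1.46 for lola, 3.24 for cas and 2.43 for chinmo. Among stem cell genes they were 1.22 for klu, 2.56 for wor, -1.995 for mira, 1.55 for ase and -1.55 for CycE. Among neuronal and adhesion genes they were -8.21 for nrv3, -5.40 for brp, 2.22 for elav, 1.63 for Nrt and 1.57 for Dscam1. Among Notch genes they were 2.08 for E(spl)mgamma-HLH, 2.66 for E(spl)m7-HLH, 1.74 for E(spl)m8-HLH, 2.61 for E(spl)mbeta-HLH and 1.06 for Su(H). Among glial, type II and optic lobe genes they were -2.90 for repo, 1.60 for Eaat1, 1.52 for opa, 1.00 for Optix and 1.97 for dac.

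Among cell cycle genes the values were -1.86 for dup, -1.67 for Mcm6, 1.58 for rap and 1.96 for Cap-G. Among metabolic genes they were -2.39 for Ald, -1.09 for Gapdh2, -1.69 for PyK, -2.20 for Vha100-2 and -1.54 for ND-MLRQ. Among stress and signalling genes they were -4.70 for Hsp67Bc, -2.15 for Hsp26, -1.77 for Hsp23, -0.995 for Stat92E and 1.43 for Socs36E. Among the other genes they were -1.95 for w, 0.95 for apt, 2.31 for jar, 2.87 for sprt, 2.78 for Unr and -6.21 for bru3.

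Of 23 lists, 11 changed their difference from 1.5 h to 5 h and 7 from 1.5 h to 3 h in camera with its preset correlation, over 46 tests, and 0 with an estimated correlation. The median log2 changes to 5 h were 0.77 for neuroblast identity, 1.115 for Notch targets, 0.42 for Notch pathway components, 1.49 for type II lineage markers, 0.95 for optic lobe markers, 0.38 for asymmetric division and 0.36 for mitosis. They were -3.08 for neuron markers (camera adjusted p = 8.39e-05, adjusted p = 0.597 with an estimated correlation), -0.68 for DNA replication, -1.02 for V-ATPase subunits (camera adjusted p = 5.53e-06, adjusted p = 0.114 with an estimated correlation) and -1.18 for glycolysis (camera adjusted p = 3.27e-06, adjusted p = 0.264 with an estimated correlation).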

How the results depend on the processing

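Scaling without CR43283, the gene-length trend and the fits without all 5 h libraries were chosen only after the results were seen. In no setting was a gene called in the opposite direction (0 genes). Of the named genes' values under all settings, 2120 kept their side of the threshold, 36 lost and 20 gained a call. These genes were picked partly because they held under such settings, so the counts do not measure the stability of other genes. Of the lists' values, 572 kept their side, 40 lost and 32 gained a call. Counts that moved by more than 1.5 times follow, and the cause was not tested unless the fit had fewer samples. For GMCs against NBs, fitting only the groups compared gave 3001 calls at 1.5 h, and leaving out 1 library gave 1157 to 1458 at 1.5 h, 1095 to 2183 at 3 h and 1742 to 3195 at 5 h. For the change of the difference from 1.5 h to 3 h, DESeq2 gave 32 and the replicate block 1; to 5 h, DESeq2 gave 2165 and leaving out 1 library 719 to 1876. For NBs of 3 h against 1.5 h, DESeq2 gave 225, no filter 17, the replicate block 19, the groups alone 152, the gene-length trend 43 and leaving out 1 library 0 to 3. For NBs of 5 h, DESeq2 gave 1930 and leaving out 1 library 461 to 2285. For GMCs of 3 h, DESeq2 gave 921, the replicate block 113, the groups alone 1589, the gene-length trend 626 and leaving out 1 library 4 to 102; for GMCs of 5 h the last gave 1627 to 2749. Over the settings that keep every library of the groups compared, the share of higher calls for GMCs against NBs lay between 43.32% and 56.26% at 1.5 h, 39.14% and 55.24% at 3 h and 49.84% and 58.2% at 5 h. It lay between 44.19% and 94.74% for NBs of 3 h, 50.92% and 64.65% for NBs of 5 h, 32.33% and 61.95% for GMCs of 3 h, 49.41% and 60.51% for GMCs of 5 h and 49.6% and 59.53% for the change of the difference to 5 h. With an estimated correlation 0, 0 and 0 lists were called. The fry test called 11, 12 and 12 lists where camera called 11, 9 and 9. It added type II markers (adjusted p = 0.00962) and V-ATPase subunits (0.0117) at 1.5 h, glia markers (0.00635), temporal patterning (0.0014) and stress genes (0.0214) at 3 h, and glia markers (0.00377), temporal patterning (0.000396) and JAK-STAT, Toll and antimicrobial genes (0.00635) at 5 h. It did not call ribosome biogenesis (0.119) and ribosomal proteins (0.486) at 1.5 h. With fold changes beyond 1 on the log2 scale, shared lower genes of 1.5 h and 3 h numbered 217, shared higher and lower genes of 1.5 h and 5 h 150 and 162, and those of 3 h and 5 h 373 and 351. Without all 5 h libraries 2552 genes were called at 1.5 h and 2903 at 3 h. Same-numbered libraries correlated at -0.164 to 0.082, so the numbers do not pair them; the block gave 1691, 1789 and 2545 calls for GMCs against NBs at 1.5, 3 and 5 h. With the block, the 3 h call of Notch pathway components (camera adjusted p = 0.051), the 5 h call of Notch targets (camera adjusted p = 0.055) and the call of bmm in NBs of 3 h (edgeR adjusted p = 0.0816) were not made. It added those of neuron markers (camera adjusted p = 0.00672), ribosomal proteins (camera adjusted p = 0.0471), pros (log2 fold change 0.87, edgeR adjusted p = 0.00452) and Dcr-2 (edgeR adjusted p = 0.0486) at 5 h and of numb for the change to 5 h (edgeR adjusted p = 0.045), and gave fne a log2 fold change of 2.63 at 5 h in place of 1.93. It changed no other call of a named gene or list. Scaling without CR43283 moved the median fold change of all genes by -0.106 at 3 h, -0.164 for the change from 1.5 h to 3 h and 0.102 for NBs of 3 h, and the gene-length trend by 0.104 at 5 h and 0.106 for GMCs of 5 h. Scaling without mitochondrial and ribosomal RNA genes was not run, since none of these is among the genes counted. Depth limits what can be called for genes near 1 CPM.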

Other observations

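The family tests and the other splits of the samples were chosen only after the results were seen. 3 cell recognition families, of which the lists hold only beat-Ia and dpr8, were higher in GMCs of 1.5 h. Of 11 beat genes, receptors that steer motor axons, 10 were higher at 1.5 h (median log2 fold change 3.66, camera adjusted p = 3.48e-07, adjusted p = 0.547 with an estimated correlation) and 4 at 3 h (median 2.75, camera adjusted p = 0.0114, adjusted p = 0.976 with an estimated correlation). Of 19 dpr genes, which pair with DIP receptors at synapses, 10 were higher and 1 lower at 1.5 h (median 1.65, camera adjusted p = 0.00119, adjusted p = 0.719 with an estimated correlation), as were 5 of 10 DIP genes (median 1.31, camera adjusted p = 0.00125, adjusted p = 0.547 with an estimated correlation). At 3 h the DIP genes were called (4 higher, camera adjusted p = 0.0268, adjusted p = 0.719 with an estimated correlation) and the dpr genes were not (0.22). At 5 h no family of the 3 was called: beat had 0 higher and 0 lower (camera adjusted p = 0.636), dpr 0 higher and 3 lower (median -1.15, 0.258) and DIP 3 higher (0.699).

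Some organelle families were lower in GMCs at some ages. Of 14 Pex genes, needed for peroxisomes, 4 were lower at 1.5 h (median -0.55, camera adjusted p = 0.000416, adjusted p = 0.902 with an estimated correlation) and 10 at 3 h (median -0.89, camera adjusted p = 6.61e-05, adjusted p = 0.719 with an estimated correlation). Of 26 Vps genes, which sort vesicle cargo, 11 were lower at 1.5 h (median -0.49, camera adjusted p = 0.000865, adjusted p = 0.976 with an estimated correlation) and 8 at 3 h, with 1 higher (median -0.47, camera adjusted p = 0.0017, adjusted p = 0.976 with an estimated correlation). At 5 h the Pex genes (0 higher and 6 lower, median -0.345, camera adjusted p = 0.159) and the Vps genes (4 higher and 5 lower, camera adjusted p = 0.89) were not called as sets. The Rab, Sec, Syx and Atg families were called at no age. Of 72 mitochondrial ribosomal protein genes, 3 were lower and 1 higher at 1.5 h (camera adjusted p = 0.574). Of the same genes 11 were lower at 3 h (median -0.59, camera adjusted p = 0.000536, adjusted p = 0.984 with an estimated correlation) and 18 at 5 h (median -0.46, camera adjusted p = 0.000605, adjusted p = 0.984 with an estimated correlation). Of 24 Mediator genes 10 were higher at 5 h (median 0.56, camera adjusted p = 0.000865, adjusted p = 0.719 with an estimated correlation). Of 34 families and 102 tests 14 were called, and 0 with an estimated correlation. The 14 include the tRNA synthetases (median -0.338, camera adjusted p = 0.00764) and the Nup genes (median -0.321, camera adjusted p = 0.0421), both lower at 1.5 h.

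The 10 splits of 6 libraries into groups of 3 are too few for a share under 0.05. For GMCs against NBs of 1.5 h, 1 split, the real one, gave as many as 1916 genes, and the highest other gave 0. For NBs of 5 h against 1.5 h, 1 split, the real one, gave as many as 1231, and the highest other gave 0. For NBs of 3 h against 1.5 h, 2 splits, the real one with 11 genes included, gave as many. The highest other, with NB replicates 1 and 2 of 1.5 h and replicate 1 of 3 h on the same side, gave 497, which points to a structure of the samples other than age. Reads without a unique alignment came to 23.4%, 26.7% and 21.7% in those libraries. They came to 30.5% in replicate 3 of 1.5 h and to 32.9% and 33.4% in replicates 2 and 3 of 3 h. Reads in no gene were most frequent in replicate 1 of 3 h, at 17.7%. The cause of the split was not tested.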
